A study of Homo sapiens with 6 samples.

How the data were processed

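Total RNA of HCT116 p53-null cells was profiled 48 h after treatment with 10 µM TIC10 or 0.05% DMSO, with 3 arrays in each of 2 groups, and per the labels biotinylated cRNA was hybridized to Illumina arrays. The deposited bead table held intensity values, which the authors' file describes as not normalized, for 47319 probes. Whether a local background was subtracted by the scanner software is not given in the sources used here. Its column medians and totals differed between arrays, and it held no detection p-values and named no control probes. Its columns named Control 1, 2 and 3 were assigned to the DMSO group, the only one without TIC10, and within it to replicates 1, 2 and 3 by their number alone. No other link between the column names and the samples was used here. The deposited series matrix held log values that the authors had processed and centred per probe, which were taken as log2 values. Their base, scaling and reference of centring are not given in the sources used here. The column medians of the matrix were -0.0556, -0.000809 and 0.0687 for DMSO replicates 1 to 3 and 0.0304, -0.0956 and 0.0291 for TIC10 replicates 1 to 3. The median over the 6 columns was 0 (tolerance 1e-06) in 17.3% of probes, where centring on the median of these 6 arrays gives 100% and on that of 10 arrays 17.1%. The summed intensity of each array is given with the results.

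Analysis was done in R 4.3.3 with limma 3.58.1. Intensities were background-corrected with normexp (saddle-point fit, offset 50), quantile normalized and taken to log2. A probe was kept when it lay above percentile 40 of its array on at least 3 arrays, which left 29440 probes. Of the probes in the table, 30112 had 1 gene symbol, 8 had several and 17199 had none in the array annotation. Entrez numbers of 30073 probes matched the RefSeq table of assembly GRCh38.p14, which was used for current names only. Probes with several symbols were left out of gene tests. Each gene was represented by its brightest kept probe, which gave 14534 genes from 20120 probes. Of 4181 genes with more than 1 kept probe, 11 had probes called in opposite directions.

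TIC10 was compared with DMSO by the moderated test of limma (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over genes and an adjusted p under 0.05 as the threshold, and at least 2-fold for the larger changes. An exact permutation test of a single gene could not go below p = 0.1 with 3 arrays against 3. The 21 gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists, and again with the correlation estimated from the data. At the preset correlation 11 lists passed, and those of the stress response, replication and mitosis also passed with the estimated correlation. Members were counted from the gene tests, adjusted over all genes and adjusted over the list alone. Lists share members, such as TNFRSF10B, and list members without a usable symbol on the array were not analysed here.

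The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule took the 12 highest rises and the 12 largest falls among changed genes whose groups did not overlap, passing over placeholder and open reading frame symbols and sex-linked marker genes. It added a panel of TRAIL, FOXO, cell cycle, stress and ERK genes whatever their result, and for each list up to 4 changed members with the largest change, or the 2 with the smallest p where none changed. IFIT1, the other genes named for DMSO replicate 3, and the gene families of the closing section were chosen after their values were seen.

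Alternatives were no background correction (offset 16), scaling of arrays to one median, cyclic loess, the authors' processed values, no filter, a stricter filter (above percentile 60 on 6 arrays), the mean of a gene's probes, an intensity trend with robust eBayes, replicate number as a block, and leaving out each array. The lists were also tested with fry, and all probes one by one. Array weights were added after the data were seen. The 10 splits of the arrays into groups of 3, the real one included, were compared. Random lists matched on intensity in 50 bins were drawn 10000 times. The series matrix was tested on its own with limma and camera, on the same probes, and no test joined the 2 tables.

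The steps were tested on simulated data with known changes. Changes of single genes were placed in brighter probes only, so the rates do not cover dim genes. Of genes changed by 0.5 on the log2 scale, 9.23% of 65 were found, of those changed by 1, 60.9% of 64, and of those changed by 2, 95.3% of 64. Of 14360 unchanged genes 10 were called, 8.62% of the calls. The simulation changed only 193 genes, where 3463 were called in the data. The same adjusted threshold therefore asked for a smaller unadjusted p in the simulation, and its rates do not carry over to the data. The raised list was found, and 0 of 20 other lists were called. The simulated noise was independent between genes, so this does not show how often lists of correlated genes are called falsely.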

Results

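Gene expression was measured on Illumina bead arrays in HCT116 cells, an established human colorectal carcinoma line, here in a derivative without p53. The cells were harvested 48 h after treatment with 10 µM TIC10, a small molecule also known as ONC201, or with 0.05% DMSO, its solvent. There were 3 arrays per treatment, 6 in all. Columns of the bead table named Control 1 to 3 were taken as DMSO replicates 1 to 3 by number. The summed intensity per array ran from 1.16e+07 to 1.91e+07, and the median probe from 42.6 to 49.6. DMSO replicate 3 was the brightest, with a mean intensity of 404 against 297 and 270.0 on DMSO replicates 1 and 2. Brightness also followed treatment: the median probe read 42.6 to 43.6 on TIC10 arrays and 46 to 49.6 on DMSO arrays. Percentile 90 was 372 to 441 on TIC10 arrays and 447 to 786 on DMSO arrays, while the summed intensities overlapped. Quantile normalization removes such a difference, and whether it was technical or biological was not tested. The labels call the arrays replicates without saying that they came from separate cultures, so p-values measure the spread between these arrays, which may be technical. The number of arrays limits the precision.

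TIC10 was compared with DMSO to ask which transcripts it changed, with the TRAIL, FOXO3 and ERK genes that the title of the series points to in view. In treated cells the genes of the integrated stress response rose as a list (median log2 change 1.14, adjusted p = 4.5e-22). The genes of DNA replication (median -1.38, adjusted p = 4.5e-22) and of mitosis (median -1.59, adjusted p = 1.25e-33) fell. Among single genes, UPP1, which encodes uridine phosphorylase, rose 13.7-fold, from 8.78 ± 0.44 to 12.56 ± 0.05 on the normalized log2 intensity scale (mean ± SD, n = 3 each). A further kept probe of UPP1 rose by only 0.97 on the log2 scale, and in the series matrix UPP1 rose by 2.76. TMSB15A, a member of the beta-thymosin family, fell by 3.56 on the log2 scale, from 10.19 ± 0.03 to 6.63 ± 0.17. Of 14534 genes tested, 3463 changed (limma, Benjamini-Hochberg adjusted p under 0.05), 1513 of them upward and 1950 downward. A change of at least 2-fold was found for 672 genes, 265 higher and 407 lower. The 3 TIC10 values lay all above or all below the 3 DMSO values in 6045 genes, 41.6% of those tested, where chance gives 10%. The split between directions depended on scaling: with arrays set to one median instead of quantile normalization, 318 genes were higher and 2009 lower, and the median log2 change of all genes moved from -0.01 to -0.15. With that scaling, 66 of the 88 named genes that changed kept their call, and those that did not were CYP24A1, ATF4, MCL1, TNFRSF21, BCL2L2, IRS2, SEC24D, PARL, HSPD1, EPHA2, FOSL1, LSS, AEN, IFITM1, NFKB2, TNIP1, TSR1, NOP56, NPC1, ATG12, KRT19 and TFRC. The medians of the FOXO, endoplasmic reticulum, mitochondrial protease, p53, ribosome biogenesis and autophagy lists turned from above to below the median of all genes. Without DMSO replicate 3, which stood apart from the other DMSO arrays, 2379 genes were higher and 2790 lower. Without TIC10 replicate 1 the counts were 891 and 1175, and without TIC10 replicate 3 they were 935 and 1213.

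The 12 highest rises, given as log2 change ± SE of the limma fit, were UPP1 (3.78 ± 0.21), RNA18SN5 (3.03 ± 0.78), NRP1 (2.77 ± 0.38), LAMB3 (2.66 ± 0.17), DDIT3 (2.56 ± 0.39), SUN3 (2.55 ± 0.08), ASNS (2.46 ± 0.07), DUSP5 (2.39 ± 0.13), DDIT4 (2.39 ± 0.26), TRIB3 (2.37 ± 0.15), IFFO1 (2.23 ± 0.13) and ATF3 (2.18 ± 0.22). NRP1 encodes neuropilin-1, a co-receptor for VEGF and semaphorins, and LAMB3 a chain of laminin-332. DDIT3, ASNS, DDIT4, TRIB3 and ATF3 belong to the stress response list. The adjusted p of these rises ran from 6.36e-05 for ASNS to 0.0328 for RNA18SN5. Further kept probes gave 0.97 for UPP1, 1.09 for NRP1, 0.45 for LAMB3, 2.68 for ASNS and 0.29 for ATF3. The 12 largest falls were TMSB15A (-3.56 ± 0.10), TMSB15B (-3.24 ± 0.11), KITLG (-3.04 ± 0.31), GINS2 (-2.66 ± 0.13), KIF20A (-2.60 ± 0.15), OAS3 (-2.49 ± 0.34), FEN1 (-2.44 ± 0.13), FAM83D (-2.42 ± 0.09), CYP24A1 (-2.40 ± 0.61), LMNB1 (-2.32 ± 0.16), ASF1B (-2.32 ± 0.23) and BIRC5 (-2.29 ± 0.21). TMSB15A and TMSB15B are near-identical copies that one probe can bind in common, so their falls may not be separate measurements. KITLG encodes the ligand of the KIT receptor, CYP24A1 the vitamin D 24-hydroxylase and LMNB1 lamin B1. The adjusted p of these falls ran from 6.36e-05 for TMSB15A to 0.0304 for CYP24A1. Further kept probes gave -2.91 and -0.06 for TMSB15B, -3.08 and -0.76 for KITLG, -0.99 for OAS3, -1.99 for FEN1 and -1.24 for BIRC5. RNA18SN5, an 18S ribosomal RNA gene, and CYP24A1 lost their calls without any one TIC10 array, with adjusted p up to 0.113 and 0.103. The other 22 of these 24 kept theirs without each array, but 4 of them did not pass in the series matrix: ASF1B (-0.17, adjusted p = 0.763; 3.06e-05 to 0.763 over 16 alternatives), OAS3 (-0.36, adjusted p = 0.224; 1.6e-06 to 0.224 over 16 alternatives), LMNB1 (-0.49, adjusted p = 0.0652; 2.53e-06 to 0.0652 over 16 alternatives) and KIF20A (-0.43, adjusted p = 0.0528; 2.42e-06 to 0.0528 over 16 alternatives). DMSO replicate 3 differed from the mean of DMSO replicates 1 and 2 by 2.33 for CYP24A1, and its RNA18SN5 level was 8.17 against 11.34 on DMSO replicate 1.

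**Figure D1:**
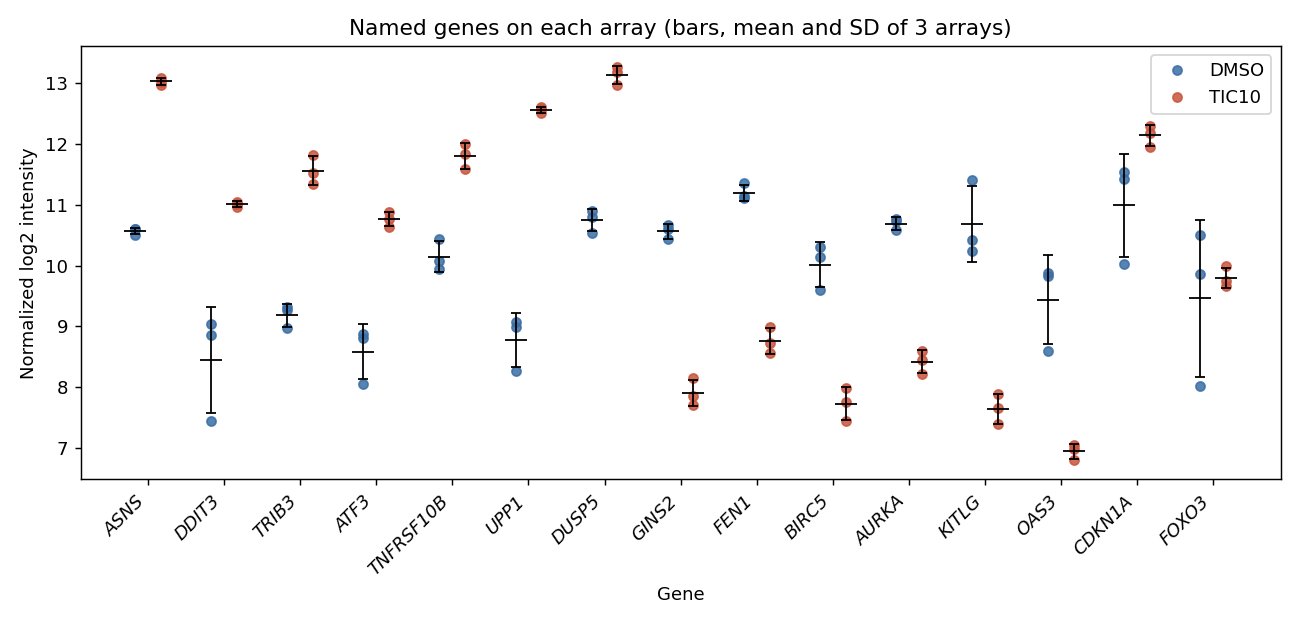
Normalized log2 intensity (vertical axis) of 15 named genes (horizontal axis) on the 3 DMSO arrays (blue) and the 3 TIC10 arrays (red), with the mean and SD of each group in black. ASNS rose from 10.57 ± 0.05 to 13.02 ± 0.06 and GINS2 fell from 10.57 ± 0.12 to 7.91 ± 0.22, while the 2 groups overlap for FOXO3.

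Transcripts of the integrated stress response, the programme driven by the transcription factor ATF4, rose. Of 48 genes tested on this list, 38 were higher and 0 lower, 42 and 2 when adjusted over the list alone, and the median log2 change was 1.14. With arrays scaled to one median 20 were higher and 0 lower, with a median of 0.82. The list test (limma camera, preset inter-gene correlation of 0.01, Benjamini-Hochberg over 21 lists) gave an adjusted p = 4.5e-22, and adjusted p = 0.00423 with an estimated correlation. ASNS, which makes asparagine, rose 5.49-fold (adjusted p = 6.36e-05), and DDIT3, which encodes the stress factor CHOP, rose 5.89-fold (adjusted p = 0.00486). TRIB3, a pseudokinase induced by CHOP and ATF4, rose 5.18-fold, and DDIT4, an inhibitor of mTORC1 signalling, 5.22-fold. ATF3 rose by 2.18 ± 0.22 on the log2 scale, with a further probe at 0.29. ATF4 itself rose by 0.86 ± 0.14 (adjusted p = 0.00626), with 2 further probes at 0.38 and 1.92. With arrays scaled to one median ATF4 did not pass (adjusted p = 0.0774; 6.23e-05 to 0.0774 over 16 alternatives). Chaperones and folding factors of the endoplasmic reticulum did not move as a list: 6 of 28 were higher and 5 lower, 7 and 6 adjusted over the list alone (median 0.24, adjusted p = 0.139). Within it DNAJB9, a co-chaperone of BiP, rose by 2.05 ± 0.11, EDEM1 by 1.13 ± 0.10 and SEC24D by 1.05 ± 0.15, and the folding factor CRELD2 changed by -1.09 ± 0.15. Without DMSO replicate 3, 10 members were higher and 9 lower (median 0.10), and without TIC10 replicates 2 and 3 in turn 3 and 2 were lower. Scaling to one median left 2 higher and 7 lower.

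Genes of the cell division machinery were lower in TIC10-treated cells. All 50 tested genes of the G2/M and mitosis list were lower, also when adjusted over the list alone, with a median log2 change of -1.59 (camera adjusted p = 1.25e-33; adjusted p = 0.00423 with an estimated correlation). KIF20A, a mitotic kinesin, changed by -2.60 ± 0.15, BIRC5, which encodes survivin, by -2.29 ± 0.21, the kinase AURKA by -2.27 ± 0.11 and DLGAP5 by -2.17 ± 0.08. The adjusted p of these 4 was 9.15e-05 to 0.000812. Of 47 genes of DNA replication and G1/S, 40 were lower and 0 higher, 43 and 0 adjusted over the list alone (median -1.38, camera adjusted p = 4.5e-22; adjusted p = 0.0403 with an estimated correlation). GINS2, a subunit of the replicative helicase complex, changed by -2.66 ± 0.13, the flap endonuclease FEN1 by -2.44 ± 0.13, the transcription factor E2F2 by -2.23 ± 0.15 and thymidine kinase TK1 by -2.10 ± 0.17. G1 cyclins, their kinases and inhibitors gave 3 lower and 0 higher of 17, also when adjusted over the list alone (median -0.18, adjusted p = 0.0562), with adjusted p = 0.0162 without DMSO replicate 3 and 0.0259 without TIC10 replicate 2 (0.00997 to 0.39 over 18 alternatives). Without DMSO replicate 3, 6 members were lower and 1 higher, and the list had an adjusted p = 0.266 with an estimated correlation. The members lower were CCND3 (-1.34 ± 0.28), CDK2 (-1.21 ± 0.16) and RBL1 (-0.83 ± 0.07), with CCND3 at adjusted p up to 0.0698 without DMSO replicate 2 or TIC10 replicate 1 or 3. CCND1, cyclin D1, differed by -0.02 ± 0.14 (adjusted p = 0.931) and the inhibitor CDKN1B by -0.21 ± 0.11 (adjusted p = 0.247). CDKN1A, which encodes p21, differed by 1.15 ± 0.39 (adjusted p = 0.0789), and by 0.66 without DMSO replicate 3 (adjusted p = 0.00217; 0.00161 to 0.217 over 16 alternatives). MYC differed by 0.96 ± 0.47 (adjusted p = 0.201), and by 1.56 without DMSO replicate 3 (adjusted p = 8.72e-06; 8.72e-06 to 0.651 over 16 alternatives).

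**Figure D2:**
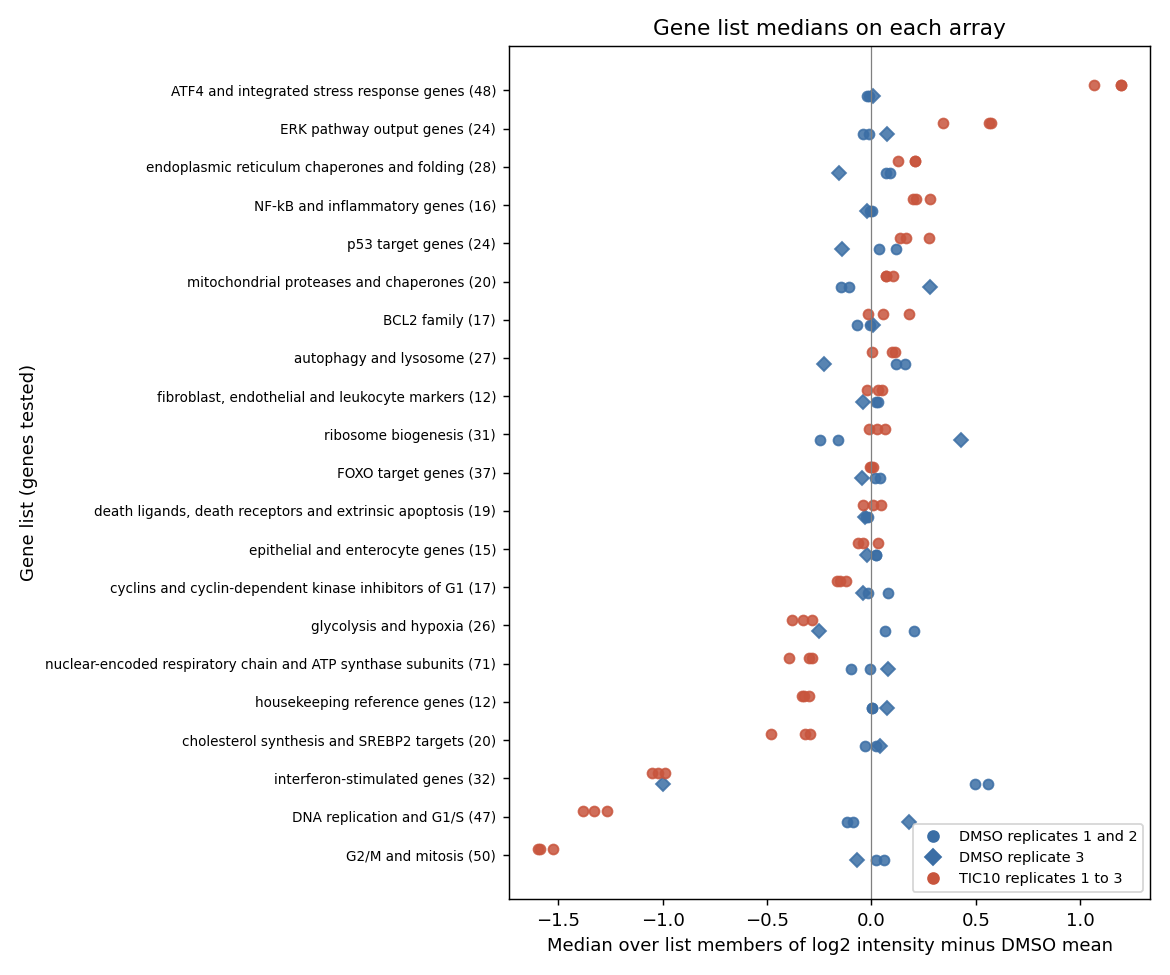
Median, over the tested members of each of 21 gene lists (vertical axis), of the log2 intensity minus the mean of the DMSO arrays (horizontal axis), 1 point per array. The TIC10 arrays (red) lie apart from the DMSO arrays (blue) for the stress response, replication and mitosis lists, and DMSO replicate 3 (diamond) lies with the TIC10 arrays for interferon-stimulated genes.

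The TRAIL receptors DR5 and DR4 rose in the bead intensities, DR4 not in the series matrix, and TRAIL itself was too dim to be measured. TNFRSF10B, which encodes the TRAIL receptor DR5, rose 3.14-fold (1.65 ± 0.16 on the log2 scale, adjusted p = 0.000923), and 2 further probes of the gene gave 0.76 and 1.33. TNFRSF10A, which encodes the receptor DR4, rose by 1.20 ± 0.23 (adjusted p = 0.0104; 0.0508 without TIC10 replicate 1; 0.000291 to 0.917 over 16 alternatives), but in the series matrix it differed by -0.04 (adjusted p = 0.917). The single named probe of TNFSF10, the gene of TRAIL, read 37.4, 37.9 and 35.8 on DMSO replicates 1, 2 and 3 and 29.6, 32.1 and 31.5 on TIC10 replicates 1, 2 and 3, never above percentile 17.9 of its array, and it failed the brightness filter. Without that filter TNFSF10 differed by -0.09 ± 0.05 (adjusted p = 0.354), so that no difference was detectable at this intensity. Of 19 genes of death ligands, death receptors and extrinsic apoptosis, 3 were higher and 1 lower, also when adjusted over the list alone, and the list did not pass (median 0.00, adjusted p = 0.526). Without DMSO replicate 3, 5 were higher and 4 lower, without TIC10 replicate 1 1 was higher, and without TIC10 replicate 2 2 were lower. Beside the receptors, TNFRSF21 rose by 0.55 ± 0.13 and APAF1, the scaffold of the apoptosome, changed by -1.06 ± 0.13 (for TNFRSF21, adjusted p up to 0.0992 without any one array but DMSO replicate 3). The BCL2 family had 5 members higher and 1 lower of 17, also over the list alone (median 0.06, adjusted p = 0.171). Among them were BCL2L2 (0.90 ± 0.15), the BH3-only genes HRK (0.82 ± 0.11) and BBC3 (0.82 ± 0.11), and BCL2L12 (-0.86 ± 0.19; adjusted p up to 0.0757 without any one array but DMSO replicate 3). Without TIC10 replicate 1, 3 members of the family were higher, and 2 with arrays scaled to one median. MCL1 rose by 0.38 ± 0.11 (adjusted p = 0.0448), a call that was lost (adjusted p up to 0.147 without DMSO replicate 1 or any one TIC10 array), and its sign turned with arrays scaled to one median, to -0.08, which lay above the median of all genes there (0.00724 to 0.815 over 16 alternatives).

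The FOXO targets did not move as a list. Of 37 genes, 10 were higher and 4 lower, 12 and 6 adjusted over the list alone (median 0.02, adjusted p = 0.303). GADD45A, a DNA damage and stress gene, rose 2.84-fold (adjusted p = 0.0112), the autophagy gene MAP1LC3B by 1.46 ± 0.16 on the log2 scale, the insulin receptor substrate IRS2 by 1.24 ± 0.12 and GADD45B by 1.20 ± 0.12. GADD45A came to an adjusted p of 0.0501 without TIC10 replicate 3, and 8 members were lower without DMSO replicate 3 and 2 without TIC10 replicate 1. Scaling to one median gave 6 higher and 7 lower. FOXO3 itself differed by 0.33 ± 0.58 (adjusted p = 0.749), with its DMSO arrays spread over 9.46 ± 1.29, and by -0.39 without DMSO replicate 3 (adjusted p = 0.141; 0.141 to 0.922 over 16 alternatives). The 2 further probes of FOXO3 gave -0.01 and 0.87. FOXO1 differed by 0.05 ± 0.08 (adjusted p = 0.734). BCL2L11, which encodes the FOXO target BIM, differed by 0.06 ± 0.11 (adjusted p = 0.751). DRD2, the dopamine receptor, differed by -0.01 ± 0.09 (adjusted p = 0.937), and CLPP, the mitochondrial protease, by -0.09 ± 0.13 (adjusted p = 0.706). DRD2 read 5.91 to 6.12 over the 6 arrays and BCL2L11 6.02 to 6.36. Both were dim and failed the stricter filter, so a change of either could go undetected. Mitochondrial proteases and chaperones gave 1 higher and 3 lower of 20, also over the list alone (median 0.10, adjusted p = 0.51; 0.0423 without DMSO replicate 3, where 8 were higher; 0.0423 to 0.944 over 18 alternatives). The list had an adjusted p = 0.195 with an estimated correlation when DMSO replicate 3 was left out, and 1 member was lower without DMSO replicate 1 or any one TIC10 array. HSPE1, which encodes HSP10, changed by -0.95 ± 0.12 and PARL by 0.49 ± 0.12, and the smaller changes of HSPD1 (-0.43 ± 0.11) and TIMM17A (-0.37 ± 0.08) passed as well. PARL (adjusted p up to 0.0988 without any one array but DMSO replicate 3), HSPD1 (adjusted p up to 0.0914 without DMSO replicate 1 or any one TIC10 array) and TIMM17A (adjusted p up to 0.0644 without DMSO replicate 1 or any one TIC10 array) lost their calls.

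Output genes of the ERK pathway were higher as a list, 7 higher and 1 lower of 24, 12 and 2 adjusted over the list alone (median 0.48, camera adjusted p = 0.000722). With an estimated correlation the call was lost (adjusted p = 0.103). With arrays scaled to one median 2 were higher and 1 lower, with a median of 0.11 where that of all genes was -0.15 (camera adjusted p = 0.00266 at the preset correlation). DUSP5, a phosphatase that inactivates nuclear ERK, rose by 2.39 ± 0.13, the growth factor HBEGF by 1.79 ± 0.26, the receptor EPHA2 by 1.34 ± 0.13 and the AP-1 subunit FOSL1 by 1.30 ± 0.29, the last with adjusted p up to 0.0784 without DMSO replicate 2 or any one TIC10 array. Leaving out DMSO replicate 3 gave 12 higher members. DUSP6, the cytoplasmic ERK phosphatase, differed by 0.55 ± 0.18 (adjusted p = 0.0688; 0.0299 without TIC10 replicate 2; 0.00643 to 0.78 over 16 alternatives). NF-kB and inflammatory genes had 4 higher and 0 lower of 16, 5 and 0 over the list alone (median 0.19, camera adjusted p = 0.00312; adjusted p = 0.103 with an estimated correlation). They were RELB (1.34 ± 0.14), NFKB2 (1.11 ± 0.28; adjusted p up to 0.11 without DMSO replicate 1 or 2 or TIC10 replicate 1 or 3), TNIP1 (0.74 ± 0.08) and CXCL2 (0.58 ± 0.08). Among p53 targets, in cells described as lacking p53, 6 were higher and 2 lower of 24, 8 and 3 over the list alone. Their median was 0.18, with a camera adjusted p = 0.0301 and adjusted p = 0.354 with an estimated correlation. With arrays scaled to one median it was -0.17, where the median of all genes was -0.15. That call ended without DMSO replicate 3 (adjusted p = 0.0899) and without TIC10 replicate 3 (adjusted p = 0.0522; 0.00818 to 0.354 over 18 alternatives). Without DMSO replicate 3, 10 were higher and 4 lower, and without TIC10 replicate 1 the median was 0.12. The members that rose most were TNFRSF10B, GADD45A, the stress gene SESN2 (1.42 ± 0.12) and AEN (0.84 ± 0.16; adjusted p up to 0.0503 without TIC10 replicate 1). SESN2 is also on the stress response list.

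Interferon-stimulated genes were lower than the DMSO mean as a list, but DMSO replicate 3 had the list median of the TIC10 arrays. Single members departed from this in both directions: OAS3 read 8.60 on DMSO replicate 3 against a TIC10 mean of 6.95, and IRF7 7.07 against 8.12. Of 32 genes, 6 were lower and 0 higher, 3 and 0 adjusted over the list alone (median -1.02, camera adjusted p = 0.000297; adjusted p = 0.548 with an estimated correlation). The members lower included OAS3 (-2.49 ± 0.34), IFITM1 (-1.80 ± 0.52), PSMB9 (-1.18 ± 0.25) and BST2 (-1.07 ± 0.29), and the last 3 lost their calls (IFITM1, adjusted p up to 0.146 without any one array but DMSO replicate 3; PSMB9, adjusted p up to 0.0651 without DMSO replicate 1 or any one TIC10 array; BST2, adjusted p up to 0.134 without any one array but DMSO replicate 3). The median of the list on the TIC10 arrays was 0.01 above DMSO replicate 3, and DMSO replicate 3 itself was -1.498 from the mean of DMSO replicates 1 and 2. IFIT1, named after its values were seen, read 11.70 and 11.39 on DMSO replicates 1 and 2, 7.07 on DMSO replicate 3 and 6.80 as the mean of the TIC10 arrays. Without DMSO replicate 3, 27 members were lower and 1 higher, with a median of -1.47 (camera adjusted p = 2.78e-19; 2.78e-19 to 0.548 over 18 alternatives), and an adjusted p = 0.0194 with an estimated correlation. Without DMSO replicates 1 and 2 in turn 2 and 3 were lower, and without TIC10 replicates 1, 2 and 3 in turn 1, 2 and 1. With arrays scaled to one median 10 were lower, and with cyclic loess 3.

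Several lists of metabolism were lower. Nuclear-encoded subunits of the respiratory chain and ATP synthase had 26 lower and 1 higher of 71, 34 and 2 over the list alone (median -0.33, camera adjusted p = 6.99e-08; adjusted p = 0.246 with an estimated correlation). The largest falls were SDHA (-0.85 ± 0.15), NDUFB6 (-0.82 ± 0.10), NDUFA6 (-0.74 ± 0.09) and ATP5MF (-0.73 ± 0.10). Without TIC10 replicate 1, 17 members of this list were lower. Genes of cholesterol synthesis had 7 lower and 2 higher of 20, 10 and 3 over the list alone (median -0.41, camera adjusted p = 0.0301; adjusted p = 0.174 with an estimated correlation). ACAT2 (-1.66 ± 0.08), LSS (-1.14 ± 0.25) and EBP (-1.08 ± 0.08) were lower and the desaturase gene SC5D (0.89 ± 0.18) higher, with LSS at adjusted p up to 0.078 without any one TIC10 array and SC5D at adjusted p up to 0.057 without TIC10 replicate 1. The further kept probe of ACAT2 gave only -0.14, and the 2 further probes of LSS gave -0.08 and -0.06. Without TIC10 replicate 1, 4 members were lower. Glycolysis and hypoxia genes had 9 lower and 2 higher of 26, 12 and 3 over the list alone (median -0.30, camera adjusted p = 0.0118; adjusted p = 0.446 with an estimated correlation). The glycolytic genes ALDOC (-1.61 ± 0.30), PFKFB4 (-1.24 ± 0.30) and PGAM1 (-1.23 ± 0.13) were lower and NDRG1, a hypoxia-responsive gene, higher (1.69 ± 0.46), with PFKFB4 at adjusted p up to 0.0965 without any one array but DMSO replicate 3 and NDRG1 at adjusted p up to 0.116 without DMSO replicate 2 or any one TIC10 array. In the series matrix ALDOC differed by 0.11 (adjusted p = 0.788; 3.51e-05 to 0.788 over 16 alternatives) and PFKFB4 by -0.26 (adjusted p = 0.32; 2.56e-05 to 0.32 over 16 alternatives). The call of the list ended there (adjusted p = 0.399) and with the mean of a gene's probes (adjusted p = 0.0653; 0.000119 to 0.446 over 18 alternatives). The change of NDRG1 was 1.10 without DMSO replicate 3. DMSO replicate 3 lay -0.38 from the other DMSO arrays on this list. Housekeeping reference genes had 6 lower and 1 higher of 12, 7 and 1 over the list alone (median -0.34, camera adjusted p = 0.0162; adjusted p = 0.163 with an estimated correlation). PGK1 (-0.97 ± 0.12), SDHA and PPIA (-0.83 ± 0.08) were lower and TFRC, the transferrin receptor, higher (0.65 ± 0.19; adjusted p up to 0.138 without any one array but DMSO replicate 3). With arrays scaled to one median the calls of cholesterol synthesis (adjusted p = 0.114; 3.08e-06 to 0.174 over 18 alternatives) and housekeeping genes (adjusted p = 0.124; 1.49e-05 to 0.959 over 18 alternatives) ended. In the series matrix both ended as well (adjusted p = 0.0733 and 0.959). The call of housekeeping genes also ended with cyclic loess (adjusted p = 0.0637) and with the mean of a gene's probes (adjusted p = 0.0964).

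The remaining lists did not pass. Ribosome biogenesis had 1 member higher and 1 lower of 31, also over the list alone (median 0.02, adjusted p = 0.513): TSR1 (0.62 ± 0.14; adjusted p up to 0.0759 without DMSO replicate 1 or 2 or TIC10 replicate 1 or 3) and NOP56 (-0.38 ± 0.08). This list was 0.65 higher on DMSO replicate 3 than on the other DMSO arrays, and without that array it was higher with TIC10 (median 0.26, camera adjusted p = 0.00303; 0.00303 to 0.955 over 18 alternatives). That call was lost (adjusted p = 0.143 with an estimated correlation), and 14 members were higher there. Autophagy and lysosome genes had 5 higher and 2 lower of 27, 5 and 4 over the list alone (median 0.05, adjusted p = 0.381), among them MAP1LC3B, WIPI1 (1.16 ± 0.10), NPC1 (0.89 ± 0.08) and ATG12 (0.85 ± 0.12). Of the list, 6 were lower without DMSO replicate 3, and 3 were higher and 7 lower with arrays scaled to one median. Epithelial and enterocyte genes had 1 higher, KRT19 (0.39 ± 0.10; adjusted p up to 0.0892 without DMSO replicate 1 or 2 or TIC10 replicate 1 or 3), and 1 lower, CLDN3 (-0.68 ± 0.08), of 15, also over the list alone (median -0.03, mean 0.00247, test downward, adjusted p = 0.837). Of 12 markers of fibroblasts, endothelium and leukocytes, 1 was higher, also over the list alone: CD68, a lysosomal protein of macrophages and other cells (1.80 ± 0.26; median of the list 0.04, adjusted p = 0.478).

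The series matrix, which holds log values that the authors processed, gave fewer and smaller changes. On the same 14534 genes it called 974, 535 higher and 439 lower, and 71 and 9 at 2-fold if its values are log2, a base that is not stated. In both tables, 356 genes were higher and 307 lower, against 55.7 and 58.9 for unrelated lists, and 9 changed in opposite directions. Across genes, which are not independent replicates, the log2 changes correlated at r = 0.61. The stress response list had a median of 1.07 in the matrix and 1.14 in the intensities, with DDIT3 at 2.73, TRIB3 at 2.38, ASNS at 2.31 and TNFRSF10B at 1.44 in the matrix. The mitosis list had -0.27 against -1.59, with 7 of 50 members called lower in the matrix (adjusted p = 5.19e-11; adjusted p = 0.102 with an estimated correlation), and replication -0.50 against -1.38, with 27 of 47. FOXO targets passed in the matrix (median 0.13, camera adjusted p = 0.00142; adjusted p = 0.219 with an estimated correlation), as did autophagy genes (median 0.12, adjusted p = 0.00651; adjusted p = 0.283 with an estimated correlation). Ribosome biogenesis genes were lower there (median -0.14, adjusted p = 0.00651; adjusted p = 0.254 with an estimated correlation). The p53 targets passed there with the test upward and the median at -0.02 (adjusted p = 0.0199, and adjusted p = 0.243 with an estimated correlation), and interferon-stimulated genes did not pass (median 0.05, adjusted p = 0.399). For mitochondrial proteases the median and the test differed in sign in the matrix (median -0.03), as for housekeeping genes (median 0.01). Of the 88 named genes called in the intensities, 51 kept their call in the matrix, and those that did not were KIF20A, OAS3, LMNB1, ASF1B, TNFRSF10A, APAF1, TNFRSF21, HRK, IRS2, EDEM1, CRELD2, SEC24D, PARL, HSPD1, TIMM17A, SDHA, NDUFB6, NDUFA6, TK1, AURKA, RBL1, LSS, SC5D, AEN, IFITM1, PSMB9, BST2, NFKB2, TNIP1, CXCL2, ALDOC, PFKFB4, TSR1, CLDN3, KRT19, PGK1 and PPIA. The 2 tables were normalized separately, and the difference between them was not tested.

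**Figure D3:**
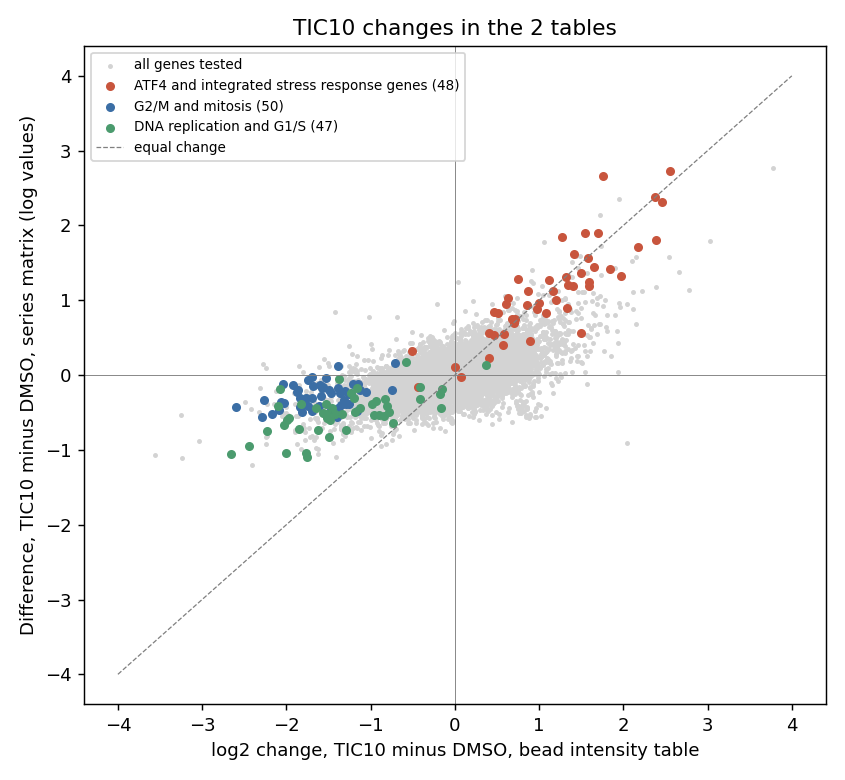
Change with TIC10 in the series matrix (vertical axis, difference of log values) against the log2 change in the bead intensity table (horizontal axis), 1 point per gene, with 3 gene lists in colour and a dashed line of equal change. Stress response genes lie near the line, with medians of 1.07 and 1.14, and mitosis genes lie far above it, with medians of -0.27 and -1.59.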

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

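The tests of the tables and of DMSO replicate 3 were chosen after the results were seen, and the splits of the arrays were planned. Probes without a gene symbol, which the comparisons of genes left out, also changed with TIC10. Of 9314 such probes past the brightness filter, 1021 changed (669 higher and 352 lower, limma, adjusted over all kept probes), 11% against 21.2% of the probes with a symbol.

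The arrays can be split into groups of 3 in 10 ways, too few for a share under 0.1. The real split gave 3463 changed genes and 672 of at least 2-fold, where the highest of the other splits gave 0 and 0, so that 1 split of 10 gave as many. It gave 11 lists past the threshold, and the highest of the others gave 10. Each other split mixed DMSO and TIC10 arrays within its groups, so part of the TIC10 difference stayed in the comparison and part widened the spread. These counts are therefore no measure of false calls.

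The bead table and the series matrix gave different TIC10 effects, with medians of -1.59 and -0.27 for the mitosis list and of 1.14 and 1.07 for the stress response list. If the authors had normalized the same hybridizations and left low values in place, the noise of dim probes would be shared. Over 21712 dim probes the largest correlation between 2 columns paired by group and number was 0.0226. Over 4726 bright probes, with the group mean removed from each column, these pairs gave -0.725 to 0.121. Deviations of 3 columns from their own mean sum to 0, which favours negative values between unmatched columns. How the authors treated low values is not known, so the dim probes alone cannot decide. The DMSO pairing rests on the column numbers alone. Columns in another order within the groups are argued against by DMSO replicate 3, whose bright-probe deviations reached at most 0.198 with any matrix column. Columns exchanged between DMSO and TIC10 would alter the group means, so these deviations cannot test such an exchange. The largest dim-probe correlation over the 36 pairs was 0.0416, with the limit of dim probes given above. Other pairs reached 0.661 over bright probes, the highest of them between bead TIC10 replicate 2 and matrix DMSO replicate 3, which is across treatments, and what these pairs share stays open. One overall scale is excluded by the ratios of matrix to bead medians, which differed 5.54-fold between the 2 lists, and no biological explanation was tested.

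DMSO replicate 3 stood apart from DMSO replicates 1 and 2: 370 genes differed over 2-fold from both, against 4 or fewer for each of the other 5 arrays. A TIC10 culture under a DMSO label is argued against by its stress response and mitosis medians, which lay 0.00863 and 0.0657 of the way from the other DMSO arrays to TIC10. Brightness or normalization as the whole cause is argued against by its interferon-stimulated genes, whose median was at most -1.15 under each of the 4 normalizations, with 0 of 10000 intensity-matched random lists as low. What set this array apart stays open, and no biological explanation was tested since the labels give it no group of its own.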

How the results depend on the processing

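Array weights and the tests built on them were chosen after the data were seen, and the other alternatives were planned. Values in parentheses are adjusted p, and the cause was not tested unless given. With arrays scaled to one median, there were 318 higher genes, 85 higher genes of at least 2-fold and 905 lower genes of at least 2-fold, and calls ended for cholesterol synthesis (0.114) and housekeeping genes (0.124), and calls were gained for G1 cyclins (0.0214), and the direction turned for MCL1 (0.815). With the authors' processed values, there were 974 changed genes, 535 higher genes, 439 lower genes, 80 2-fold genes, 71 higher genes of at least 2-fold and 9 lower genes of at least 2-fold, and calls ended for cholesterol synthesis (0.0733), glycolysis (0.399) and housekeeping genes (0.959), and calls were gained for FOXO targets (0.00142) and autophagy (0.00651), and the direction turned for interferon-stimulated genes (0.399), ribosome biogenesis (0.00651), TNFRSF10A (0.917), AEN (0.934), IFITM1 (0.918), PSMB9 (0.842), BST2 (0.54), ALDOC (0.788) and TSR1 (0.547). With an estimated correlation the gained calls were lost there (FOXO targets 0.219, autophagy 0.283), as was the turned call of ribosome biogenesis (0.254). With array weights, chosen after the data were seen, there were 6013 changed genes, 2775 higher genes and 3238 lower genes, and calls ended for p53 targets (0.0656), and calls were gained for G1 cyclins (0.00997) and ribosome biogenesis (0.0227). With all probes tested one by one, there were 5290 changed probes and 2549 higher probes, a count of probes, with and without a symbol, in place of genes. With fry, calls ended for p53 targets (0.0642), interferon-stimulated genes (0.171) and glycolysis (0.0642), and calls were gained for the BCL2 family (0.0459) and G1 cyclins (0.0219). With an estimated inter-gene correlation, calls ended for the respiratory chain (0.246), ERK output (0.103), cholesterol synthesis (0.174), p53 targets (0.354), interferon-stimulated genes (0.548), NF-kB genes (0.103), glycolysis (0.446) and housekeeping genes (0.163). Without the filter on dim probes, calls were gained for G1 cyclins (0.0151). With the mean of a gene's probes, calls ended for glycolysis (0.0653) and housekeeping genes (0.0964). With cyclic loess, calls ended for housekeeping genes (0.0637). Leaving out 1 array in turn gave 2066 to 5169 changed genes, 891 to 2379 higher genes, 1175 to 2790 lower genes, 592 to 753 2-fold genes, 220 to 287 higher genes of at least 2-fold and 372 to 471 lower genes of at least 2-fold, and adjusted p of death receptors 0.377 to 0.73, the BCL2 family 0.125 to 0.241, FOXO targets 0.174 to 0.418, the stress response 3.73e-23 to 6.57e-21, endoplasmic reticulum folding 0.0685 to 0.382, mitochondrial proteases 0.0423 to 0.855, the respiratory chain 1.08e-08 to 1.04e-05, replication 1.45e-23 to 4.98e-21, mitosis 7.48e-35 to 3.42e-32, G1 cyclins 0.0162 to 0.131, ERK output 6.4e-05 to 0.00131, cholesterol synthesis 0.023 to 0.0426, p53 targets 0.00818 to 0.0899, interferon-stimulated genes 2.78e-19 to 0.00763, NF-kB genes 0.00159 to 0.00684, glycolysis 0.000184 to 0.0312, ribosome biogenesis 0.00303 to 0.955, autophagy 0.131 to 0.841, epithelial genes 0.492 to 0.918, other cell types 0.346 to 0.626 and housekeeping genes 0.0162 to 0.0232. With array weights DMSO replicate 3 had a weight of 0.2. Replicate number as a block gave 1265 higher and 1611 lower genes. With the group mean of each gene removed, arrays of one number correlated at -0.15, 0.16 and -0.01. On these deviations not every replicate correlated best with its own number. Of 88 named genes called, 0 lost their call without DMSO replicate 3, 14 and 13 without DMSO replicates 1 and 2, and 23, 16 and 21 without TIC10 replicates 1, 2 and 3. The authors' values kept the calls of 51. The stress response, replication and mitosis lists kept their direction and call when each choice was changed alone, but with the authors' values and an estimated correlation together the mitosis list lost its call (adjusted p = 0.102). A slide block was not run, since no slide is named, and the saddle-point fit is identical to the setting used, since there were no detection p-values. Signal over background limits dim genes such as TNFSF10. The self-test found 9.23% of changes of 0.5 on the log2 scale, in brighter probes only, and gives no rate for dim genes. It changed far fewer genes than were called in the data, so its rates do not carry over.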

Other observations

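The gene families and the test of the FOXO targets were chosen after the results were seen, and the criterion of the FOXO test was tightened after its first outcome. The p-values of the families are therefore no independent test of them. Tubulin genes, which encode the subunits of microtubules, were lower: 9 of 11 passed and 0 were higher (median -0.93, camera adjusted p = 1.36e-07; adjusted p = 0.0279 with an estimated correlation). Proteasome subunits had 10 of 32 lower and 0 higher (median -0.29, adjusted p = 3.59e-05; adjusted p = 0.0279 with an estimated correlation). Kinesins had 15 of 32 lower and 1 higher (median -0.14, adjusted p = 0.0015; adjusted p = 0.0798 with an estimated correlation), and T-complex chaperonin subunits 4 of 8 lower (median -0.41, adjusted p = 0.0142; adjusted p = 0.26 with an estimated correlation). Several kinesins, KIF11, KIF14, KIF20A and KIF23 among them, are also on the mitosis list, so the kinesins are not a separate result. Of the chaperonin subunits 1 in place of 4 passed with arrays scaled to one median. The series matrix called far fewer members lower: 4 tubulins, 2 proteasome subunits, 1 kinesin and 0 chaperonin subunits. As lists all 4 passed downward there too, at the preset correlation (tubulins, adjusted p = 9.41e-06; proteasome subunits, 6.83e-06; kinesins, 0.0136; chaperonin subunits, 0.0125).

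Cytosolic ribosomal protein genes had 11 of 74 higher (median 0.10, adjusted p = 0.000473; adjusted p = 0.21 with an estimated correlation), with 1 higher with arrays scaled to one median, 24 with cyclic loess and 27 without DMSO replicate 3. In the series matrix 2 of them were higher and 1 lower (median 0.06, camera adjusted p = 0.0133 at the preset correlation). Host genes of small nucleolar RNAs had 5 of 14 higher (median 0.31, adjusted p = 0.0192; adjusted p = 0.451 with an estimated correlation), but 0 higher and 1 lower with arrays scaled to one median, and 8 higher without DMSO replicate 3. The matrix had 4 host genes higher (median 0.22, camera adjusted p = 0.00457 at the preset correlation). Metallothioneins did not pass (median 0.98, adjusted p = 0.139), with 2 of 6 higher, but in the series matrix 4 were higher (median 0.55, adjusted p = 6.83e-06 at the preset correlation). On DMSO replicate 3, the ribosomal RNA gene RNA28SN5 read 6.45 against 13.03 and 12.52 on DMSO replicates 1 and 2, and S100A4 read 11.14 against 7.54 and 7.97. Of 10000 random lists matched on intensity, 0.01% had a median as low as the respiratory chain list and 5.61% one as low as the housekeeping list. Genes drawn at random need not vary together as related genes can, so these shares do not allow for correlation within a list. With an estimated correlation the respiratory chain list did not pass camera (adjusted p = 0.246).

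One hypothesis was that the FOXO targets that rose may be carried by members that are also targets of ATF4 or CHOP. The 5 shared members, GADD45A, MAP1LC3B, ATG12, BBC3 and EIF4EBP1, were all higher in both tables, with medians of 0.85 (adjusted p = 9.57e-05) and 0.57 (adjusted p = 4.17e-09). They were named after the results were seen, so these p-values are no independent test of the hypothesis. The other 32 had 5 higher and 4 lower (median -0.09, limma camera, adjusted over both parts, adjusted p = 0.937), and in the series matrix 5 higher and 1 lower (median 0.05, adjusted p = 0.0783). The others went both ways, so their median does not decide, and since the shared members are targets of both kinds of factor, a rise by FOXO and one by ATF4 or CHOP cannot be told apart for them.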
